A study of Daphnia magna with 24 samples.

How the data were processed

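Gene expression was measured on 24 two-colour arrays of whole Daphnia magna, a freshwater water flea used as a standard test animal in aquatic toxicology. Adult females aged 14 to 16 days were kept for 24 h at 23.5 °C in water taken at 1 of 4 sites at Walker Mine, per the labels' protocols, and 10 to 15 animals were pooled for each exposure. The sites were upstream of the mine, downstream of the mine portal, downstream of the tailings, and Little Grizzly Creek. Each site had 3 exposures. Each exposure was hybridised on 2 arrays against unexposed animals kept in COMBO, a defined culture medium, with the Cy3 and Cy5 dyes exchanged between both arrays. The design text states that copper contamination differed between the sites. It gives no concentrations, so no ordering of the sites by copper was used.

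The authors deposited one log ratio per feature and array, in a table of 7680 features. How the arrays were scanned, background-corrected, normalised and filtered is not given in the sources used here. The base of the deposited log ratios is not stated either, and they were read here as log2 ratios. Array medians lay between -0.0265 and 0.0177, so the deposited values were already centred. Their spread was not equal. The SD across features ran from 0.297 on an array of upstream exposure 2 to 1.05 on an array of portal exposure 3. Averaged over both arrays, it was 0.544, 0.282 and 0.577 in upstream exposures 1, 2 and 3. In portal exposures 1, 2 and 3 it was 0.605, 0.3 and 0.792. The main fit did not rescale the arrays. Blank cells were treated as values the authors left out. They numbered 132 to 2574 per array. Signals per channel were not used here, so the brightness behind a ratio is unknown, and the number of arrays limits the precision.

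The direction of the deposited ratios had to be inferred. The 2 arrays of an exposure, of opposite dye, correlated between 0.616 and 0.91 across features in all 12 exposures, so the authors had already turned them the same way. That this way is exposed over control is likely, because the labels list the exposed animals as channel 2 and because the first array of every pair carries them in Cy5, but nothing states it. Among 132 pairs of arrays of one dye orientation, 5 correlated below -0.3, the lowest at -0.376, and 1 of these pairs joined upstream exposures 2 and 3. The signs of single exposures are therefore not fully settled. An alternative with the second upstream exposure turned was run for each comparison.

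Feature identifiers such as P11CH10 were used as deposited. None of the 7680 matched a name, locus tag or accession in the RefSeq gene table used here, which lists 28335 genes. Genes are therefore not named, and 20 gene lists fixed before the data were examined could not be tested. Nor do results on genomic position follow. Features are counted, and at most 2 that rose and 2 that fell are named for each comparison, the largest changes among features past the threshold with the same sign in all 3 exposures of a site, or, between sites, with all 3 exposures of one site above all 3 of the other.

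Both arrays of an exposure were averaged, which cancels a dye effect, and a feature missing on either array was blank for that exposure. Features with a value in at least 2 exposures of every site were tested, 6504 in all. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) fitted all 12 exposures with 1 mean per site and a spread shared by the 4 sites. Each site's mean was tested against 0, which compares exposed with control animals, each pair of sites was tested against each other, and a moderated F test asked whether any sites differed. Adjusted p-values are Benjamini-Hochberg values over all tested features within a comparison, with a threshold of 0.05. The test against 0 leaves out the spread of the control animals where control RNA was shared between arrays, and the labels do not say whether it was. They call the 3 exposures of a site biological replicates.

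The fit was tested on simulated data with the spread and blanks of the real features. With 200 of 6504 features changed by 1 log2 unit in tailings water, it recovered 69% against control and 61.5% against upstream. For changes of 0.5 units these shares were 46% and 8.5%, and for changes of 2 units 91.5% and 85%. At 1 unit, false calls numbered 6 among 144 in tailings water against control and 10 among 133 in tailings against upstream water. The simulated noise was independent between features and between exposures, with the same spread at all sites. Real features are not independent and same-numbered exposures deviate together, so recovery and false calls in the real data may differ.

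Exposure numbers are shared by the sites. The deviations of same-numbered exposures from their site means correlated above 0.1 in all 3 pairs for upstream with portal (0.482 to 0.812), for tailings with Little Grizzly Creek (0.39 to 0.514) and for portal with Little Grizzly Creek (0.166 to 0.556). For these site pairs the numbers were taken to pair the exposures, from the data and not from the labels. For the other 3 site pairs at least 1 correlation lay below 0.1. The alternatives, chosen before the data were examined, were another centring, quantile normalisation, a fit of 24 arrays with a dye term, other rules for blank values, fits of the compared sites alone, robust eBayes, other thresholds, the exposure number as a block, and leaving out each exposure. Alternatives added after seeing the data were the exposure number as a random effect, array weights, leaving out exposure 3 of both portal and Little Grizzly Creek, turning the second upstream exposure, and a blocked fit of portal and Little Grizzly Creek alone.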

Results

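The study asked how waters from sites at a copper mine change gene expression in Daphnia magna, with unexposed laboratory animals as the control of every array. The 4 sites each had 3 exposures, and each exposure 2 arrays of opposite dye. Arrays held between 5106 and 7548 values of the 7680 features. The third exposure of portal water had the most blanks, 33.5% and 18.9% of features on its 2 arrays, followed by the third exposure of Little Grizzly Creek water with 20.9% and 23.3%. The median dye-swap error of an exposure value was 0.141 log2 units, and the median SD among exposures of one site was 0.189. Ratios are given as likely exposed over control. If the deposited direction is the opposite, every rise below is a fall and every fall a rise.

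Exposures of one site did not always resemble each other. Correlations across features between exposures of tailings water ran from 0.192 to 0.584 and for Little Grizzly Creek water from 0.184 to 0.644. They were lower for portal water, from -0.00663 to 0.49, and for upstream water, from -0.245 to 0.555. Between sites, exposures of one number correlated from -0.0664 (exposure 3 of portal and tailings water) to 0.835 (exposure 1 of tailings and Little Grizzly Creek water). Their mean was above that of differently numbered exposures in 5 of the 6 pairs of sites, among them upstream and portal water (0.612 against 0.16) and tailings and Little Grizzly Creek water (0.737 against 0.448). The exception was portal and tailings water (0.138 against 0.143). Features are not independent replicates, so these correlations describe the exposures and carry no test.

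**Figure D1:**
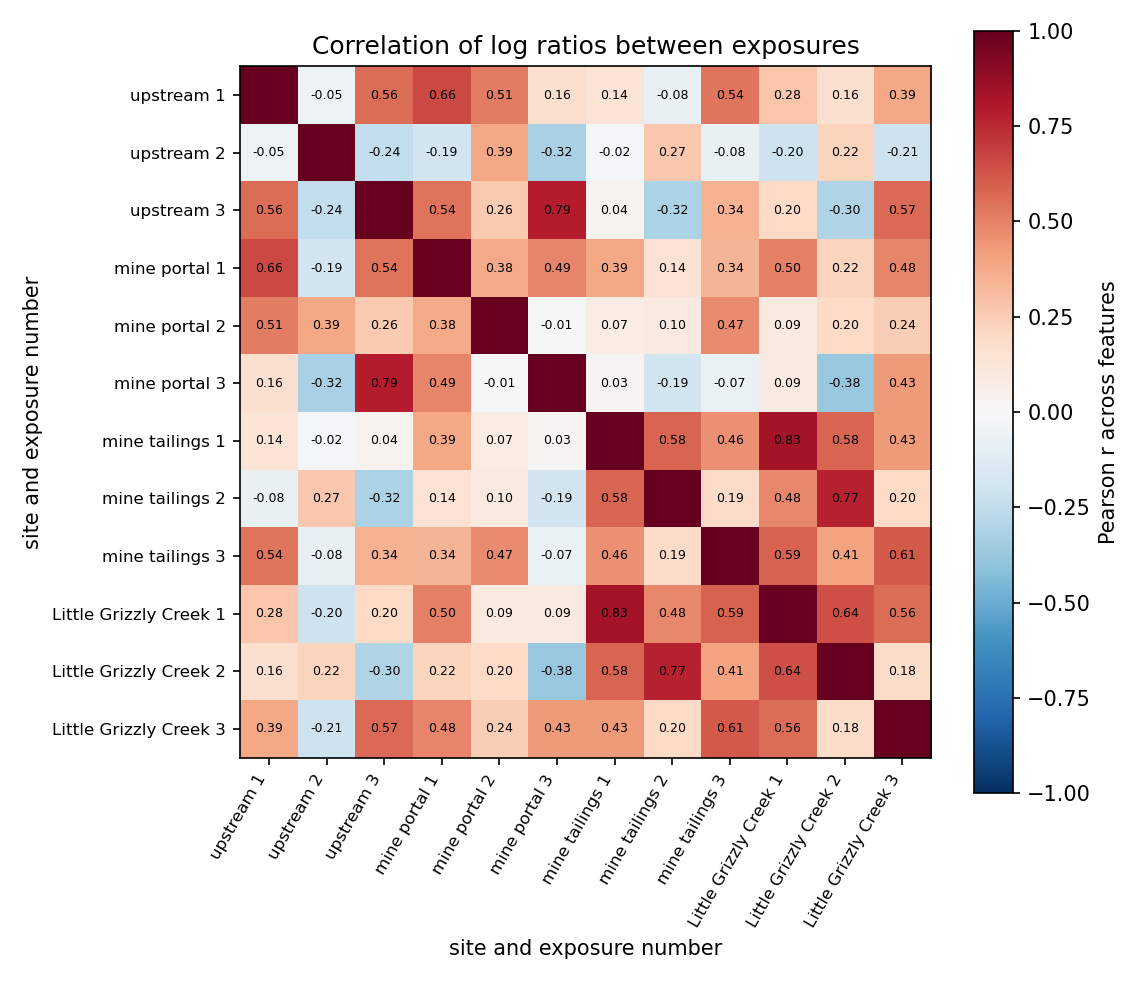
Pearson correlation across tested features between the log ratios of the 12 exposures (rows and columns, site and exposure number), with red for positive and blue for negative values. The tailings and Little Grizzly Creek exposures form a block of positive values between 0.184 and 0.835, and the second upstream exposure is negative against most others.

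In tailings water 552 of 6504 features (8.49%) changed against control, of which 398 rose and 154 fell. Their median absolute change was 0.724 log2 units, and 196 changed by at least 1 unit. All 3 exposures shared the sign of the change in 521 of the 552. P4CB5 rose by 3.71 log2 units (SE 0.468, adjusted p = 0.00139), about 13.1-fold if the base is 2, and its 3 exposures lay between 3.71 and 3.72. P11CH10 rose by 3.71 (SE 0.442, adjusted p = 0.00158), with exposures between 3.56 and 3.8. P13CD12 fell by 3.45 (SE 0.26, adjusted p = 0.000457), and P13DA2 fell by 3.40 (SE 0.591, adjusted p = 0.00767). The adjusted p-values are limma's with Benjamini-Hochberg adjustment here and throughout. Fewer features passed without exposure 1 (272), 2 (312) or 3 (301), and 91 passed when the tailings exposures were fitted alone. Without exposure 2, P13DA2 no longer passed (adjusted p = 0.0518).

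In Little Grizzly Creek water 264 features (4.06%) changed against control, 141 upward and 123 downward. The median absolute change was 1.22 log2 units, and 162 features changed by at least 1 unit. P10DH11 rose by 4.04 (SE 0.449, adjusted p = 0.00116), about 16.4-fold if the base is 2. P11CH10, which also rose in tailings water, rose by 4.04 (SE 0.442, adjusted p = 0.00111). P13DA2 fell by 3.39 (SE 0.591, adjusted p = 0.00988), as it had in tailings water, and P11CC4 fell by 2.82 (SE 0.165, adjusted p = 2.74e-05). Upward changes made up 53.4% of the calls, 69.9% after quantile normalisation, 31.6% of 674 calls with the exposure number as a block and 44.2% of 258 without exposure 3, so neither direction held the majority throughout. Without exposure 1 the count was 114 and without exposure 2 it was 142. P13DA2 did not pass without either (adjusted p = 0.1 and 0.0973). Fitted alone, this site gave 36.

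In upstream water 5 features fell against control and none rose, by at most 0.791 log2 units. P4DB6 averaged -0.791 ± 0.106 (SD, n = 3; adjusted p = 0.014 by limma) and P5CG5 -0.589 ± 0.0777 (SD, n = 3; adjusted p = 0.0332 by limma). Both features had means between 0.0692 and 0.147 in tailings and Little Grizzly Creek water. In portal water their means were -0.479 and -0.233, and both were negative in all 3 exposures. At an unadjusted p under 0.05, limma gave 1083 features (16.7%). None of the 5 calls stood when any of the 3 exposures was left out (0 features each time) or when the second exposure was turned (0), while quantile normalisation gave 324 features, 57.4% of them upward. With the exposure number as a block, 458 features passed, 173 higher and 285 lower, but with the number as a random effect 2 passed, both lower. The block takes the spread between exposure numbers out of the error of this test. The 458 therefore leave out part of the spread among replicates.

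In portal water no feature passed limma's adjusted threshold, the smallest adjusted p being 0.0717, although 1428 features (22%) had an unadjusted p under 0.05. This count depended on the second exposure, since 337 features passed without it. It was 170 among features with a value in all 3 exposures of every site, and 1087 with the exposure number as a block, but 0 with the number as a random effect. As in upstream water, the blocked count leaves out the spread between exposure numbers. Features with the same sign in all 3 exposures made up 42.3% of those with 3 values in portal water and 43.4% in upstream water, against 38.5% in tailings and 30.9% in Little Grizzly Creek water. Chance alone gives 25% for independent signs. Features of one exposure move together, and the shares rest on 4330 features in portal to 5801 in tailings water. An excess over 25% is therefore no measure of a response. The exposures differed in features that rose most in tailings and Little Grizzly Creek water. P4CB5 stood at 3.09 in the first portal exposure, at 0.026 in the second and at 1.97 in the third.

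Tailings and Little Grizzly Creek water changed many of the same features. Of the 398 that rose in tailings water and the 141 that rose in Little Grizzly Creek water, 121 were shared, where independent lists would share 8.63. Of the 154 and 123 that fell, 99 were shared, against 2.91 for independent lists. No feature changed in opposite directions. The site means correlated at 0.845 across features with a covariance of 0.18. In 20 simulations, unchanged animals were set against control RNA shared by all sites of an exposure number. Control and exposed animals added equally to the spread. The mean correlation was 0.475, the mean covariance 0.0362 and the number of shared calls 0. These simulations held no effect and called 0.2 features on average in tailings water. Their 0 shared calls were thus nearly fixed in advance and are no measure for the 121 and 99. An excess over the simulations was not particular to these sites: the upstream and portal means correlated at 0.666, against a simulated mean of 0.437. Exposures of tailings and Little Grizzly Creek water with different numbers, which share no control in these simulations, correlated between 0.2 and 0.587. The labels do not say which exposures shared control RNA, so part of the excess may come from shared controls.

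**Figure D2:**
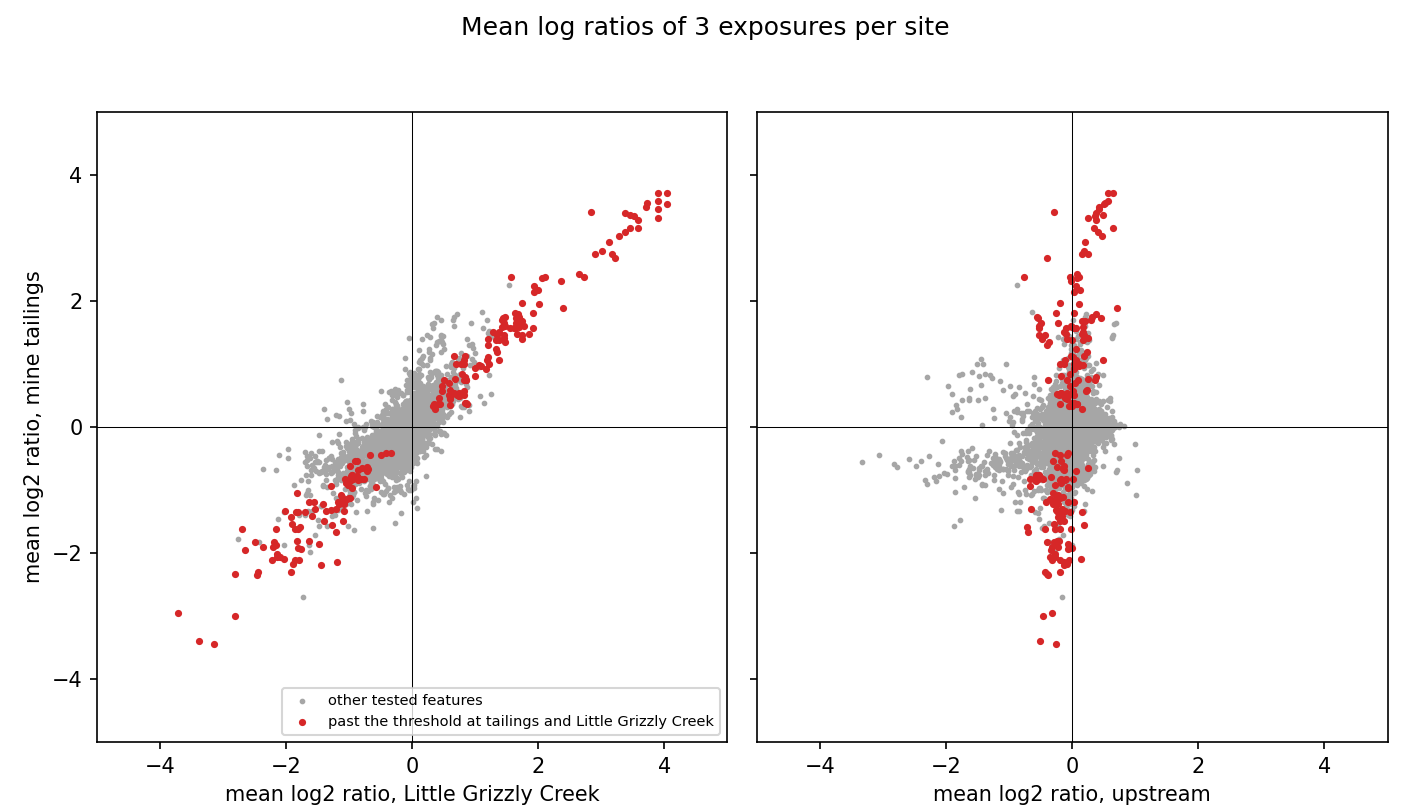
Mean log2 ratio of each of the 6504 tested features in tailings water (vertical axes) against Little Grizzly Creek water (left) and upstream water (right), with the 220 features that changed in both tailings and Little Grizzly Creek water in red. The red features lie along the diagonal on the left and along the vertical axis on the right.

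The 220 features that changed at both sites had a median absolute change of 1.35 log2 units in tailings and 1.37 in Little Grizzly Creek water, and 144 of them had the larger change in Little Grizzly Creek water. The 121 that rose had medians in the upstream exposures of 0.0488, -0.0652 and 0.0459. In the portal exposures their medians were 0.555, 0.0535 and 0.308, with 86.8% of them positive in the first. The 99 that fell had medians of -0.398, -0.28 and -0.0899 in the upstream exposures, and of -0.61, -0.215 and -0.0806 in the portal exposures. These features were selected on tailings and Little Grizzly Creek water, so their values at those 2 sites are not independent evidence.

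The direct comparison of sites asked which of the other waters differed from the upstream water. Tailings water differed from upstream water in 384 features (5.9%), 324 higher and 60 lower. P7BD1 was higher by 3.69 log2 units (SE 0.34, adjusted p = 0.00136), at 3.40 ± 0.655 in tailings against -0.285 ± 0.0071 in upstream water (SD, n = 3 each). P3DG10 was higher by 3.15 (SE 0.498, adjusted p = 0.0114). P13CD12 was lower, at -3.45 ± 0.341 against -0.261 ± 0.39 (SD, n = 3 each; adjusted p = 0.00776 by limma), and so was P2CA10, at -2.31 ± 0.549 against -0.192 ± 0.419 (SD, n = 3 each; adjusted p = 0.0488 by limma). The count fell to 89, 120 and 32 without upstream exposures 1, 2 and 3, and to 169, 156 and 207 without tailings exposures 1, 2 and 3. Turning the second upstream exposure gave 107. P2CA10 passed in 9 of 21 alternatives, with an adjusted p of up to 0.192 without upstream exposure 3, where that of P3DG10 was 0.0569. P3DG10 also did not pass with the second upstream exposure turned (adjusted p = 0.0807), and it passed in 19 of 21 alternatives.

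Little Grizzly Creek water differed from upstream water in 132 features (2.03%), 99 higher and 33 lower. P10DH11 was higher by 3.53 log2 units (SE 0.635, adjusted p = 0.0285) and P9CF4 by 3.49 (SE 0.587, adjusted p = 0.023). P11CC4 stood at -2.82 ± 0.313 against -0.403 ± 0.148 in upstream water, and P11DG2 at -2.50 ± 0.142 against -0.292 ± 0.191 (SD, n = 3 each); both had an adjusted p of 0.000946 by limma, and of 0.111 and 0.113 after quantile normalisation. Without upstream exposures 1, 2 and 3 the count was 35, 34 and 31. Without Little Grizzly Creek exposures 1 and 2 it was 24 and 57. P10DH11 and P9CF4 did not pass without any of the 6 exposures in turn, with adjusted p-values from 0.0672 to 0.0993. Of the features higher than upstream, 88 were shared by tailings (324) and Little Grizzly Creek (99), and of those lower, 26 (of 60 and 33). Independent lists would share 4.93 and 0.304. Both comparisons use the same upstream exposures. Across features the 2 differences correlated at 0.867 with a covariance of 0.214. In the 20 simulations without effect these values were 0.506 and 0.0411. Those simulations gave 0 shared calls, but data without effect leave few or no calls to share. That 0 is therefore no measure for the 88 and 26. With 1 upstream exposure used for one site and the other 2 for the other site, the correlation lay between 0.264 and 0.63 and the covariance between 0.0881 and 0.193 over the 6 such divisions. Part of the excess may come from the shared upstream exposures.

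No feature differed between portal and upstream water (199 at an unadjusted p under 0.05, 3.06% of those tested) or between tailings and Little Grizzly Creek water (215, 3.31%) by limma, and with the exposure number as a block both counts were also 0. A count of 0 does not show that these waters act alike, given the share of 1-unit changes the fit missed even in simulated data with independent noise.

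Between the downstream sites, portal water differed from tailings water in 260 features, 40 higher and 220 lower in portal water. P6BC11 was higher in portal than in tailings water by 2.24 log2 units (SE 0.348, adjusted p = 0.0125), and P11CC4 by 2.07 (SE 0.234, adjusted p = 0.00583, and 0.138 after quantile normalisation). P3DG10 stood at -0.582 ± 0.578 in portal against 2.38 ± 0.762 in tailings water, and P5DE3 at -0.549 ± 0.135 against 1.65 ± 0.598 (SD, n = 3 each). P3DG10 did not pass after quantile normalisation (adjusted p = 0.0507). It passed in 18 of 21 alternatives and P6BC11 in 19 of 21. Without portal exposures 1 and 3 the count was 159 and 138, and without tailings exposures 1 and 3 it was 137 and 143. The share higher in portal water was 15.4%, and 44% of 282 calls in the fit of 24 arrays with a dye term, which shared 111 features with the 260. None passed when only the 2 sites were fitted (0), with the spread taken from 6 exposures.

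Portal water differed from Little Grizzly Creek water in 63 features, 26 higher and 37 lower. The share higher in portal water was 41.3%, but 8.33% after quantile normalisation, 55.3% with a dye term and 59.5% with the exposure number as a block, so it settles no majority. P11CC4 was higher in portal water by 2.55 log2 units (SE 0.234, adjusted p = 0.00145) and P11DG2 by 2.48 (SE 0.211, adjusted p = 0.00129), although neither passed after quantile normalisation (adjusted p = 0.112 and 0.0957). P6BF2 was at 0.142 ± 0.274 in portal and 1.62 ± 0.387 in Little Grizzly Creek water, and P13AD7 at -0.0418 ± 0.316 and 1.43 ± 0.302 (SD, n = 3 each). With the exposure number as a block, 232 features passed in the fit of all sites (138 higher) and 0 in a fit of these 2 sites. The count without portal exposure 3 was 26, and without Little Grizzly Creek exposures 1 and 2 it was 8 (87.5% higher) and 23. P6BF2 did not pass without Little Grizzly Creek exposure 1 (adjusted p = 0.071), nor P13AD7 without that one (0.136), Little Grizzly Creek exposure 2 (0.0954), or portal exposures 2 (0.0525) and 3 (0.0842).

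**Figure D3:**
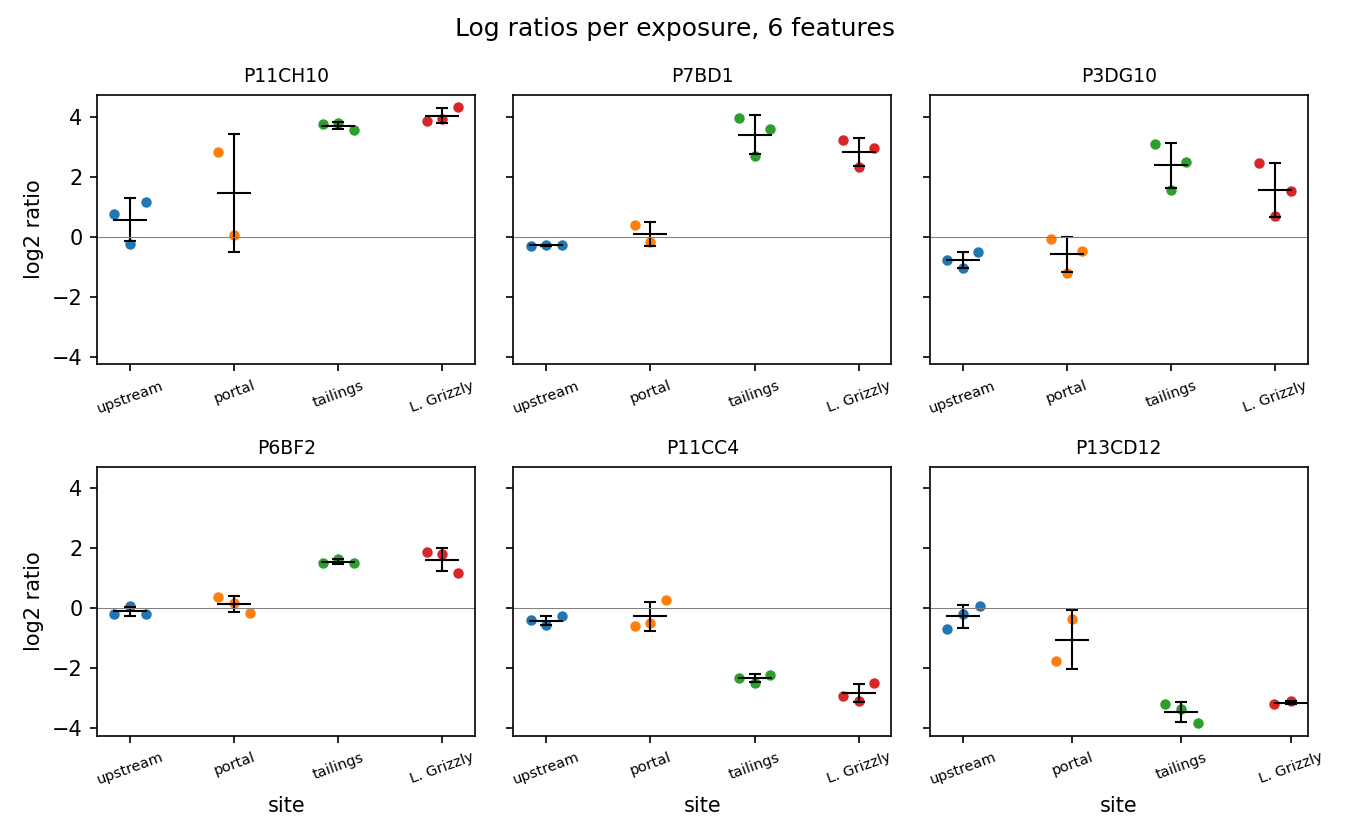
Log2 ratio of 6 named features in each exposure (coloured points, left to right exposures 1 to 3) at the 4 sites, with the mean and SD of each site in black. P11CH10, P7BD1, P3DG10 and P6BF2 are high and P11CC4 and P13CD12 low in tailings and Little Grizzly Creek water, and the first portal exposure of P11CH10 stands at 2.84.

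Across all 4 sites, 294 features (4.52%) differed by the moderated F test. The count was 60, 103 and 63 without upstream exposures 1, 2 and 3, 116, 143 and 129 without tailings exposures 1, 2 and 3, 84 and 121 without Little Grizzly Creek exposures 1 and 2, and 181 without portal exposure 1.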

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

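The tests of splits within pairs of sites and among all 4 sites were planned before the results were seen; the tests of joined sites, of blank values and of splits that keep the exposure number were chosen after. Sites differed in their effect against control, by a direct test, in 384 features for tailings and upstream water, 132 for Little Grizzly Creek and upstream water, 260 for portal and tailings water, and 63 for portal and Little Grizzly Creek water.

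In all 4 of these comparisons 1 site was tailings or Little Grizzly Creek and the other upstream or portal. Joined that way, the sites differed in 826 features, 558 higher and 268 lower at tailings and Little Grizzly Creek. Either other way of joining them into pairs gave 0 by limma (145 and 242 at an unadjusted p under 0.05). Both other ways combine only the portal and upstream difference with the tailings and Little Grizzly Creek difference. Each of these differences had given 0 alone, so the counts of 0 are no separate support for the grouping. The pattern did not need features with blanks. A planned fit of only the features with all 12 exposure values gave 325, 75, 262 and 47 features in the 4 comparisons, in the order above. Portal and upstream, and tailings and Little Grizzly Creek, gave 0 each. In the main fit, the share that differed between tailings and upstream water was 7.02% among features with all 12 values and 4.47% among the rest. Blanks lower the power to call a feature, so the lower share does not show what blanks add. No label gives a batch or a hybridisation day, so none was set against the sites. A difference between the waters, such as their copper load, stays open and untested.

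Chance is an unlikely account of a difference among the 4 sites, since 1 of 100 splits of the 12 exposures, the real one, gave as many as 294 features. This is the smallest share that 100 splits can give, and the highest other split gave 10. With each group holding all 3 exposure numbers, again 1 of 100 splits, the real one, gave as many, and the highest other gave 23. Of 100 splits into 6 and 6, only the real one gave as many as the 1124 features of tailings and Little Grizzly Creek against upstream and portal in a 2-group fit. The grouping was picked from 3 ways of joining the sites after their results were seen, and the splits take no account of the exposure number, so this count does not decide whether chance made it. The highest other split gave 336, and it put all second exposures on one side and all those numbered 3 on the other, but divided the first exposures as the real grouping does, so its calls are not attributed to the exposure number. For single pairs of sites, 10 splits of 3 against 3 are too few for a share under 0.05. The real split gave 384, 132 and 260 features for tailings and upstream, Little Grizzly Creek and upstream, and portal and tailings, where the highest other split gave 0; it gave 63 for portal and Little Grizzly Creek, where the highest other gave 2. In each of these 1 split, the real one, reached the real count. For portal and upstream and for tailings and Little Grizzly Creek all 10 splits gave 0.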

How the results depend on the processing

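Counts are given in the order of the comparisons named, and the cause of each shift was not tested unless stated. Array signals were not used here, so what brightness limits is unknown. Portal against upstream and tailings against Little Grizzly Creek gave 0 under all alternatives run. For the named features, 71 of 512 recomputed values were not past the threshold, with adjusted p-values of up to 0.894. The estimate moved in 227 of the 512, of which 51 were not past the threshold and 0 turned. The share of higher calls ran from 58.6% to 77.2% for tailings and 31.6% to 80.6% for Little Grizzly Creek against control, 64.8% to 89.1% and 53.3% to 81.3% for these against upstream, 11.1% to 44% for portal against tailings and 8.33% to 100% (2 calls) for portal against Little Grizzly Creek. The gene lists were not run, for lack of names. With the exposure number as a replicate block, the counts were 458 for upstream, 1087 for portal, 852 for tailings and 674 for Little Grizzly Creek against control, 628 for tailings and 219 for Little Grizzly Creek against upstream, 636 for portal against tailings, 232 for portal against Little Grizzly Creek (0 in a fit of those sites alone) and 565 for any difference. The numbers are not shown to pair upstream with tailings or Little Grizzly Creek, or portal with tailings, so a blocked count there is no better estimate. Against control, the block takes the spread between exposure numbers out of the error, so those blocked counts leave out part of the spread among replicates. As a random effect (consensus correlation 0.279), chosen after seeing the data, the number gave 2 and 0 for upstream and portal against control, 742 and 262 for tailings and Little Grizzly Creek against upstream, 561 and 281 for portal against tailings and Little Grizzly Creek, and 657 for any difference. Fitting only the sites compared, which leaves fewer exposures to estimate the spread, gave 0, 91 and 36 for upstream, tailings and Little Grizzly Creek against control, 147 and 83 for tailings and Little Grizzly Creek against upstream, and 0 and 2 for portal against tailings and Little Grizzly Creek. The 24-array fit with a dye term gave 126, 252 and 452 for upstream, portal and Little Grizzly Creek against control, 234 for Little Grizzly Creek against upstream and 208 for portal against Little Grizzly Creek. That fit enters both arrays of an exposure as separate values, with 1 consensus correlation of 0.545 for all features. Its counts therefore rest partly on technical repeats. Counts near the main ones can hold other features. In the dye-term fit, tailings against upstream shared 193 of its 335 calls with the main 384, and tailings against control 390 of 594 with the main 552. After quantile normalisation, Little Grizzly Creek against upstream shared 85 of 164 with the main 132. With arrays centred on their medians, these shared numbers were 372, 546 and 132. Features with values in all 3 exposures gave 18, 170 and 141 for upstream, portal and Little Grizzly Creek against control and 75 for Little Grizzly Creek against upstream. A threshold of 0.1, looser by construction, gave 113 and 525 for upstream and portal against control, 680 and 211 for tailings and Little Grizzly Creek against upstream, 455 and 140 for portal against tailings and Little Grizzly Creek, and 461 for any difference. A minimum of 1.5-fold, stricter by construction, left 319 in tailings and 2 in upstream water against control. Upstream water against control gave 324 after quantile normalisation and 1 with single arrays kept.

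Further alternatives were chosen after seeing the data. Array weights gave 614, 954 and 1075 for upstream, portal and Little Grizzly Creek against control. They gave 835 and 1422 for tailings and Little Grizzly Creek against upstream. For portal against tailings and Little Grizzly Creek they gave 413 and 1016, and for any difference 1260. The weights of exposures 1, 2 and 3 were 5.24, 0.866 and 0.464 in Little Grizzly Creek water. In portal water they were 2.47, 0.678 and 0.239. They were 1.15, 1.06 and 1.72 in upstream and 0.714, 1.41 and 0.562 in tailings water. The weighted means of Little Grizzly Creek and portal water thus rest largely on exposure 1 of each site. The higher counts that use these means are no measure of a wider change. Leaving out the third exposures of portal and Little Grizzly Creek gave 159 for upstream against control, 606 for tailings against upstream, 94 and 39 for portal against tailings and Little Grizzly Creek, and 133 for any difference. Turning the second upstream exposure gave 0 for upstream against control, 107 for tailings against upstream, 123 and 38 for portal against tailings and Little Grizzly Creek, and 112 for any difference. Leaving out single exposures, with fewer values by construction, gave ranges of 0 to 0 for upstream, 0 to 337 for portal, 272 to 312 for tailings and 114 to 258 for Little Grizzly Creek against control. It gave 32 to 207 and 24 to 104 for tailings and Little Grizzly Creek against upstream, 137 to 314 and 8 to 76 for portal against tailings and Little Grizzly Creek, and 60 to 305 for any difference.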

Other observations

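All tests in this part were chosen after the results they bear on were seen. Of the features named for a rise, 4 shared a profile: P4CB5, P11CH10, P10DH11 and P9CF4 correlated with each other between 0.975 and 0.998 over the exposures. They were named for the largest rises in tailings or Little Grizzly Creek water, so part of this likeness follows from how they were picked. Of 5825 features other than P11CH10 with at least 10 exposure values, 25 correlated with it above 0.95, among them P4CB5, P10DH11 and P9CF4. P7BD1 was also high in tailings and Little Grizzly Creek water (means of 3.4 and 2.84). It stood at 0.389 in the first portal exposure, where P11CH10 stood at 2.84. Whether features of one profile represent one transcript was not tested, since no sequences were used here.

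Large changes in upstream and portal water varied between exposures. In upstream water 134 features had a mean at or below -1, with medians of -2.27, 0.564 and -2.46 in exposures 1, 2 and 3, and none passed the threshold. In portal water 173 features had such a mean, with medians of -1.79, -0.607 and -2.45, and 84 had a mean at or above 1, with medians of 1.2, -0.0975 and 2.92; none of either passed.

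Exposures of one number deviated together across sites. The mean correlation of same-numbered deviations was 0.363 over 18 pairs of exposures. In an exact one-sided test over 216 rearrangements of the numbers, only the real one reached this value (p = 0.00463, the smallest the test can give; the highest other arrangement gave 0.335). A control RNA, day or batch shared by exposures of one number is a candidate explanation, and the labels do not say which. With 3 of the 18 pairs below 0, the sharing may not extend to all sites.

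The second upstream exposure ran against the others of its site. An exposure deposited with the opposite sign is a candidate explanation that stays open: turning it raised the mean within-site correlation from 0.311 to 0.361, but 4 exposure pairs lay below -0.3 before and after. None of the 2048 patterns of turned exposures gave fewer than 4 such pairs. Against a turned sign stand its positive correlations with the second exposures of portal (0.39), tailings (0.266) and Little Grizzly Creek (0.225) water. Of the 99 features that fell in both tailings and Little Grizzly Creek water, 88.7% of those measured were negative in it, where upstream exposures 1 and 3 had 90.9% and 61.5%. The 121 that rose in both went the other way: 34.5% were positive in it, where upstream exposures 1 and 3 had 58.3% and 54%.

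Features whose identifiers start with P rose more often in tailings water than those starting with A, 363 of 4678 (7.76%) against 35 of 1826 (1.92%), while 2.31% and 2.52% fell. Of the 46 A features that fell, 26 belong to the identifier group A6. In Little Grizzly Creek water 2.39% of the P and 1.59% of the A features rose, a smaller gap that was not tested. What the letters stand for is not given in the sources used here. A larger spread of the A features (median residual SD 0.29 against 0.174) could hide rises among them. Among features with a residual SD below the P median, 0.551% of the A features rose (95% exact interval 0.114% to 1.6%) against 7.65% of the P features (6.61% to 8.81%), which argues against the spread as the whole cause. This test replaced an earlier one, on the percent of A features that fell (2.52%), after that result was seen, because a share of falls does not measure the power to call smaller rises. The intervals treat features as independent, which they are not, and no biological explanation was tested. Blanks differed too: 67.9% of the deposited A features had enough values to be tested, against 93.7% of the P features. Matching on the residual SD does not address this.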
